A study of Homo sapiens with 6 samples.

How the data were processed

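RNA from 6 samples of the human acute myeloid leukaemia cell line NOMO-1 was sequenced: per the labels, 3 libraries of parental cells (WT) and 3 of cells in which MSLN had been knocked out (MSLN-KO). Per the labels' protocols, total RNA was taken with a column kit and made into stranded libraries after removal of ribosomal RNA. Per the submitters' processing notes, STAR, featureCounts and edgeR were used with GRCh38/hg38, and no versions are given there. The annotation release and the strand setting of the counting are not given in the sources used here.

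The table the authors deposited holds CPM (read counts per gene scaled to library size) after TMM normalization, 1 column per library and 11363 genes. The unit follows from the column totals, which lie between 967718 and 1009572, and from the values: in each column 100% of them were whole multiples of what 1 read is worth, within 0.01 of that step. Dividing by the step gave the depth of each library, between 23665824 and 30804446 reads in the listed genes. The table itself gives no read counts: read numbers, floors and counting intervals printed here all rest on that step, taken as the largest that divides the values, and would be wrong if the deposited values were not made from whole reads. Every listed gene reached at least 4.9 CPM in 3 or more libraries, so genes expressed below that level in both groups are not listed and were not analysed here. The median gene had between 800 and 1080 reads per library. PCR reads carry no molecular identifiers, so the floors and intervals given for genes near 0 cover counting error only.

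Gene identifiers were matched to symbols for 11354 of the 11363 genes. Coordinates came from GENCODE release 29 on GRCh38, which held 11314 of them. They are 1-based.

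The comparison of MSLN-KO with WT was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(CPM + 1) over all 6 libraries, without covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The planned minimum mean of 0.5 CPM removed no gene, since the smallest mean was 2.85 CPM. Log2 fold changes are on the log2(CPM + 1) scale, which understates the change of low genes, and folds are ratios of mean CPM. Counts of genes that changed by at least 1 or 2 use the log2 scale. For a gene at 0 in a whole group, the fold was computed against a floor of 3 reads over the group and is a lower bound. A gene with 1 to 3 reads in a group has its ratio with an exact 95% counting interval.

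Before the data were examined, 43 gene lists were fixed, covering the MSLN region, programmes of myeloid leukaemia, RNA quality and markers of other cell types. The 38 lists with at least 5 listed members were tested with camera (inter-gene correlation 0.01, Benjamini-Hochberg over the lists), which compares a list with all other genes. Camera with an estimated correlation and fry were run beside it. Estimating the correlation within a list from 6 libraries leaves few degrees of freedom.

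The genes named were set by rule, also before the data were examined. They are MSLN and its direct neighbours, and the 10 largest rises and 10 largest falls among called genes with non-overlapping groups and a mean of at least 1 CPM. For each list called by camera they are up to 4 called members in the direction of the list and 2 in the other, and for each other list up to 2 called members. Genes named outside this rule are marked as chosen after their values were seen. Y-linked genes and XIST were part of the fit and of the counts but are not reported, which leaves 11356 genes. Some genes that the rule names are not reported here.

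The same fit was tested on simulated libraries with the WT means, the real sizes and 1 spread of 5.9% (coefficient of variation) for every gene. In these libraries 200 of 11363 genes were changed. The fit recovered 70% of 50 genes changed 1.25-fold, 98% of 50 changed 1.5-fold, and 100% of those changed 2-fold and 4-fold. Of its 191 calls, 7 (3.7%) were false. In the real data the spread differed between genes and 45.7% of genes were called, so these rates need not hold there. A simulated list raised 1.5-fold was called, and 0 of 200 random lists were. The simulated genes were drawn independently, so this does not show how often lists whose members vary together are falsely called. For the real lists that camera called, the estimated correlation ran from 0.02 (matrix and proteases) to 0.57 (cholesterol synthesis and uptake).

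Alternatives set beforehand changed the pseudocount, the filter, the scaling, the variance trend, the list test and the replicate block, and left out each library in turn. After the data were seen, a fit without genes of chromosome 15 and a fit with the regional median change subtracted were added. The replicate number comes from the sample titles. Within each group the counts of every pair of libraries differed by more than sampling noise (chi-square per degree of freedom between 2.71 and 14.8). No library was therefore counted as a duplicate. MSLN-KO replicates 1 and 2 were the closest pair, at 2.71, and the next lowest value was 7.35. Such an excess argues against 1 library sequenced again, but cannot exclude 2 libraries made from 1 culture or RNA.

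Some genes share sequence or overlap, and how reads were split between them is not known. This holds for the histone genes, HSPA1A and HSPA1B, IFITM1 and IFITM2, RN7SL1 and RN7SL2, the zinc finger genes of 19p12, and the overlapping pairs HAGHL with CIAO3 and FAS with ACTA2. Their values are uncertain to that extent. Figures were drawn with matplotlib 3.10.9.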

Results

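Gene expression was measured by RNA sequencing in NOMO-1, a human acute myeloid leukaemia line of monocytic type that carries a fusion of KMT2A with MLLT3. Per the labels, the 2 groups were parental cells (WT, 3 libraries) and cells with a knockout of MSLN (MSLN-KO, 3 libraries). MSLN encodes mesothelin, a GPI-anchored surface glycoprotein of mesothelial cells that is also found on several carcinomas and on some leukaemias, where it serves as a target for antibodies and engineered T cells. The listed genes held 24745234, 25765425 and 23665824 reads in WT replicates 1 to 3 and 25230229, 26220479 and 30804446 reads in MSLN-KO replicates 1 to 3. Nothing in the labels says that replicates were separate cultures or clones, so the p-values measure only the spread between these samples, which may be technical.

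The targeted gene came first. MSLN (ENSG00000102854.16, GRCh38 chromosome 16, 760762 to 768865) stood at 127.3 ± 23.9 CPM in WT and 45.95 ± 0.846 CPM in MSLN-KO (mean ± SD, n = 3 each). Every MSLN-KO library (45.7, 46.9 and 45.3 CPM) lay below every WT library (153.2, 122.9 and 106 CPM), in the direction the labels give. The change was -1.43 on the log2 scale (SE 0.10, limma adjusted p = 1.5e-07), so 36.1% of the WT level of transcript remained. Gene-level values do not show which part of the transcript those reads cover.

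The region around MSLN was not lower as a whole. Of 11 listed neighbours on 16p13.3, 4 rose and 0 fell, with the same counts adjusted over the list alone and a median log2 change of 0.25 (camera adjusted p = 0.087, and 0.87 as the adjusted p with an estimated correlation). METRN, a secreted neurotrophic factor gene, rose from 3.574 ± 0.652 to 7.41 ± 1.07 CPM and HAGHL rose 1.76-fold. RPUSD1, next to MSLN, stood at 14.26 ± 2.86 CPM in WT and 16.69 ± 2.1 CPM in MSLN-KO (log2 change 0.22, adjusted p = 0.18). The list passed the camera test without WT replicate 1 (median 0.34, adjusted p = 0.031) and without MSLN-KO replicate 3 (median 0.25, adjusted p = 0.037). Over all alternatives its adjusted p ranged from 0.031 to 0.87. The 40 listed genes within 1 Mb of MSLN had a median log2 change of 0.09, with 9 called higher and 4 called lower. The 4 lower genes, named after their values were seen, were SNRNP25, JPT2, UQCC4 and FAM234A, with log2 changes of -0.68, -0.38, -0.32 and -0.23.

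**Figure D1:**
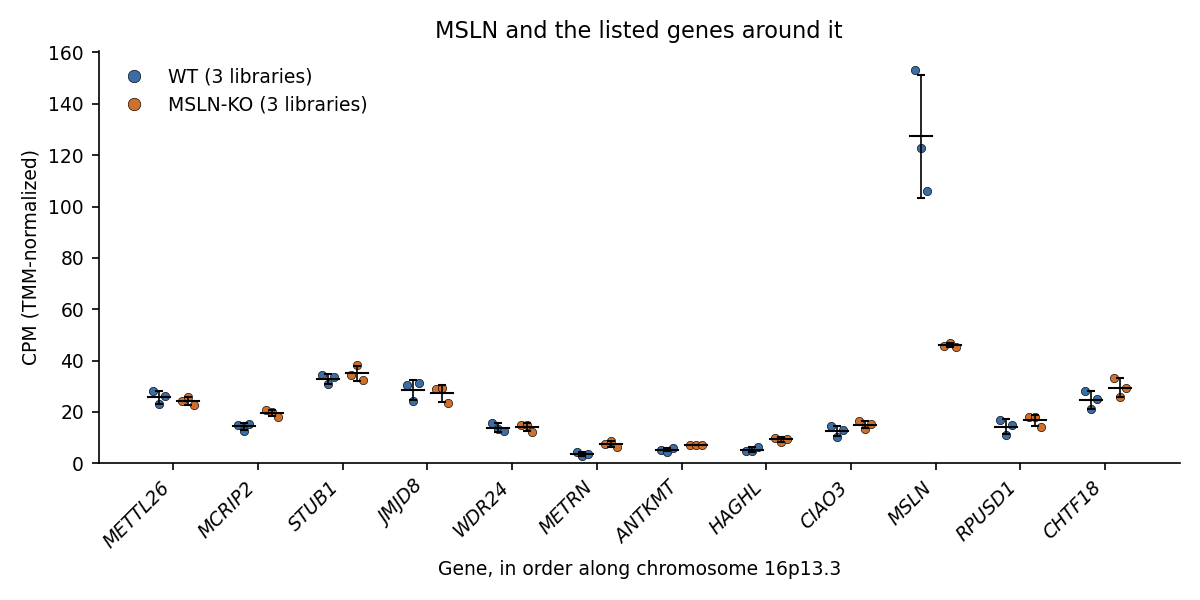
Normalized expression (y axis, CPM) of MSLN and the 11 listed genes around it, in order along chromosome 16p13.3 (x axis), in WT (blue) and MSLN-KO (orange). Points are libraries, and bars are the mean ± SD of 3. MSLN fell from 127.3 to 45.95 CPM, and 0 of the 11 neighbours shown were called lower.

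Across the transcriptome, 5197 of 11363 genes (45.7%) were called, 2545 higher and 2652 lower in MSLN-KO. Of these, 375 changed by at least 1 (203 higher, 172 lower) and 111 by at least 2 (84 higher, 27 lower) on the log2(CPM + 1) scale, a stricter bar for low genes than 2-fold and 4-fold ratios of mean CPM. In 54.7% of genes all MSLN-KO libraries lay on one side of all WT libraries, against 10% by chance. The first principal component held 87.4% of the variance and separated the groups. Pearson's r of log2 values across genes was 0.994 or more within a group and 0.950 to 0.959 between groups; genes are not independent replicates. With a pseudocount of 5, the count with a log2 change of at least 1 was 244.

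The largest rises were of genes close to silent in WT. MS4A3, a membrane protein gene of granulocyte-monocyte progenitors, went from 1.596 ± 0.81 to 109.4 ± 5.51 CPM (68.5-fold). ASS1, the argininosuccinate synthase of arginine synthesis, went from 3.111 ± 1.58 to 104.9 ± 9.04 CPM (33.7-fold), and CCND2, which encodes cyclin D2, from 1.338 ± 0.563 to 46.02 ± 3.88 CPM (34.4-fold). ZNF185 rose 96.4-fold from 0.2282 CPM. The netrin receptor gene UNC5C had 2 reads over the WT group and 2521 in MSLN-KO (ratio 1110, 95% counting interval 307 to 9170). The homeobox gene PITX1 had 1 read in WT and 2436 in MSLN-KO (ratio 2150, interval 385 to 84800). H4C6, HACD4, MTAP and ZNF43 had 0 reads in WT and were at least 550-fold, 447-fold, 439-fold and 427-fold higher.

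MPO, the myeloperoxidase of primary granules, fell from 744.4 ± 84.1 to 45.71 ± 7.65 CPM (16.3-fold lower), and ANPEP, which encodes the surface marker CD13, from 72.32 ± 5.91 to 6.952 ± 0.746 CPM (10.4-fold lower). DEFB1, a defensin gene, fell from 106.4 ± 22.9 to 9.94 ± 1.79 CPM. The retinoic acid binding protein gene CRABP1 fell 44.0-fold, and PDK4, an inhibitor kinase of pyruvate dehydrogenase, fell 35.2-fold (62.7-fold without MSLN-KO replicate 2). CLDN1 (23.9-fold), AGR2 (22.4-fold), GPNMB (12.7-fold) and GABRA4 (10.9-fold) followed, and DAB2 fell from 17.22 to 0.9043 CPM. CRABP1 and ANPEP lie on chromosome 15, most of whose genes were lower in MSLN-KO. All of these rises and falls had an adjusted p of at most 9.1e-08, the value of AGR2.

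Of 38 gene lists tested, 13 passed the camera test, 3 upward and 10 downward. With an estimated correlation, 0 of 38 passed; at an unadjusted p under 0.05, 1 list did (monocyte and macrophage markers, p = 0.014). The directional fry test called 19 lists and the mixed fry test 37.

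Monocyte and macrophage genes were mostly lower. Of 31 listed markers, 22 fell, 4 rose and 5 were not called (23 and 4 adjusted over the list alone), with a median log2 change of -0.43 (camera adjusted p = 2.1e-05, and adjusted p = 0.54 with an estimated correlation). CD163, a scavenger receptor of macrophages, fell from 17.28 ± 5.77 to 1.932 ± 0.205 CPM, and the complement gene C1QC from 5.719 ± 1.03 to 0.2268 ± 0.172 CPM (25.2-fold lower, and 43.0-fold without MSLN-KO replicate 2). APOE fell 4.80-fold. S100A8, a calcium-binding protein of monocytes and neutrophils, fell from 621 ± 111 to 250.4 ± 12.6 CPM. FCGR1A (log2 change 0.78) and CEBPB (0.55) rose.

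Genes of granules and granulocytes moved both ways. Of 17 listed, 11 fell and 5 rose, with the same counts adjusted over the list alone and a median of -0.26 (camera adjusted p = 0.032, and adjusted p = 0.76 with an estimated correlation). Beside MPO, CEACAM6 fell 7.76-fold, MMP8 15.4-fold (to 0.0345 of its WT level without MSLN-KO replicate 2, against 0.065) and the neutrophil elastase gene ELANE from 168.7 ± 12.5 to 64.2 ± 8.14 CPM. PRG2, which encodes the major basic protein of eosinophils, rose from 1.075 ± 0.321 to 22.07 ± 3.6 CPM, and GFI1, a repressor needed in granulocyte development, rose by 0.59 on the log2 scale. This call was lost with a minimum mean of 5 CPM (adjusted p = 0.085), without WT replicate 1 (0.064) and without MSLN-KO replicate 3 (0.051), within a range of 0.014 to 0.76 over all alternatives.

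Cholesterol synthesis and uptake had the highest share of members called in its direction among the 13 lists: 20 of 21 listed genes fell and 0 rose (21 and 0 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 1.4e-12, and adjusted p = 0.58 with an estimated correlation). HMGCS1, an early enzyme of the pathway, fell from 1046 ± 88.7 to 361.1 ± 19.3 CPM, LSS 2.40-fold, SQLE from 382.6 ± 15.5 to 193.4 ± 15.2 CPM, and MVK 1.94-fold. None of the listed members lies on chromosome 15.

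The list of unfolded protein and amino acid stress genes split into members that rose and members that fell, with all 26 called. Of these, 19 rose and 7 fell, with the same counts adjusted over the list alone and a median of 1.06 (camera adjusted p = 2.7e-06, and adjusted p = 0.58 with an estimated correlation). The 4 largest rises were of ASNS, the asparagine synthetase (33.32 ± 13.6 to 208.9 ± 10.3 CPM), PHGDH and PSAT1 of serine synthesis (5.47-fold and 4.51-fold), and CHAC1, a glutathione-degrading enzyme (4.68-fold). CHAC1 lies on chromosome 15. CALR, a chaperone of the endoplasmic reticulum, fell from 881 ± 88.8 to 425.3 ± 26.6 CPM and MANF, a secreted factor of the same compartment, changed by -0.57 on the log2 scale. The other 5 that fell, named after their values were seen, were the chaperone or folding genes CRELD2, HSP90B1, SDF2L1, PDIA4 and HSPA5, with log2 changes of -0.51, -0.43, -0.41, -0.29 and -0.19. ASNS varied among the WT libraries, at 45.6, 35.7 and 18.7 CPM in replicates 1 to 3. PHGDH (51.0, 40.4 and 25.6 CPM), PSAT1 (31.7, 27.9 and 19.8 CPM) and CHAC1 (3.75, 2.05 and 1.56 CPM) fell in the same order. CALR and MANF did not. The WT libraries thus differed among themselves in these named rises together, and the cause was not tested. Every MSLN-KO library still lay above every WT library for each of these rises.

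Cell cycle genes were modestly lower. Of 30 listed genes of G2/M and mitosis, 21 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 1.1e-05, and adjusted p = 0.76 with an estimated correlation). CCNB2 (cyclin B2) fell 2.13-fold, NUSAP1 1.67-fold, KIF23 1.63-fold and PRC1 1.53-fold. All 4, and 5 of the 30 members, lie on chromosome 15; the other 25 had a median of -0.21 too (16 lower, 0 higher, camera adjusted p = 0.00025 without genes of that chromosome). With the regional median subtracted, PRC1 was not called (log2 change 0.00, adjusted p = 1, with a range up to that value over all alternatives). Of 32 genes of DNA replication, 20 fell and 2 rose (21 and 2 adjusted over the list alone; median -0.22, camera adjusted p = 0.00047, and adjusted p = 0.78 with an estimated correlation). GINS3 fell 1.45-fold, MCM4 from 445.2 ± 25.7 to 325.5 ± 15.9 CPM and FEN1 1.36-fold, while the licensing factor gene CDT1 rose 1.48-fold and RRM2 1.18-fold.

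The lists of hypoxia and glycolysis and of nuclear genes of oxidative phosphorylation were lower as well. Mitochondrially encoded transcripts, given below, were not called as a list (camera adjusted p = 0.96). In the list of hypoxia and glycolysis, 21 of 30 fell and 2 rose, with the same counts adjusted over the list alone and a median of -0.37 (camera adjusted p = 2.5e-05, and adjusted p = 0.76 with an estimated correlation). PKM, the pyruvate kinase of glycolysis, which lies on chromosome 15, fell from 1984 ± 108 to 641.7 ± 67.9 CPM. BNIP3 fell 1.93-fold, PFKFB4 1.88-fold and EGLN3 1.97-fold, and VEGFA (1.60-fold) and DDIT4 (1.51-fold) rose. Among 31 nuclear genes of oxidative phosphorylation, 23 fell and 1 rose, with the same counts adjusted over the list alone (median -0.24, camera adjusted p = 4.9e-05, and adjusted p = 0.76 with an estimated correlation). COX5A, on chromosome 15, fell 1.70-fold, COX6C 1.43-fold, NDUFB8 1.42-fold and ATP5F1A 1.37-fold.

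Immediate-early and feedback genes of MAPK signalling were mostly higher. Of 18 listed, 13 rose and 2 fell, with the same counts adjusted over the list alone and a median of 0.40 (camera adjusted p = 0.0017, and adjusted p = 0.58 with an estimated correlation). IER3 rose 2.98-fold, FOSB 2.39-fold, ETV5 from 18.78 ± 2.62 to 38.51 ± 2.53 CPM and PHLDA1 1.98-fold. SPRY4, a feedback inhibitor of the pathway, fell 1.48-fold and FOS fell 1.39-fold.

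Matrix and protease genes fell in 12 of 21 cases and rose in 5, with the same counts adjusted over the list alone (median -0.28, camera adjusted p = 0.010, and adjusted p = 0.58 with an estimated correlation). Beside MMP8, the protease inhibitor gene TIMP3 fell from 43.59 ± 4.96 to 8.764 ± 1.41 CPM, MMP9 2.28-fold and SERPINB2 1.92-fold. MMP14 (1.68-fold) and PLAU (1.64-fold) rose. Of the 21 members, 2 lie on chromosome 15 and both fell. Cytokine, chemokine and receptor genes fell in 12 of 22 cases and rose in 3, with the same counts adjusted over the list alone (median -0.24, camera adjusted p = 0.019, and adjusted p = 0.76 with an estimated correlation). IL1R1 fell 3.35-fold, CCR7 from 44.27 ± 1.28 to 19.23 ± 1.66 CPM, CXCL8 2.12-fold and IL16, on chromosome 15, 1.85-fold. IL18 (1.64-fold) and CSF2RA (1.28-fold) rose. With a minimum mean of 5 CPM neither list passed (adjusted p = 0.058 and 0.051, within ranges of 0.0049 to 0.58 and 0.0077 to 0.76 over all alternatives).

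Among lists set to read RNA quality and cell stress, 10 of 14 heat shock genes fell and 0 rose, with the same counts adjusted over the list alone (median -0.38, camera adjusted p = 9.5e-05, and adjusted p = 0.76 with an estimated correlation). HSPA8 fell from 1192 ± 145 to 756.7 ± 14.1 CPM, HSPE1 1.54-fold, and HSPH1 1.52-fold, and HSPA1A fell from 68.17 ± 7.22 to 45.52 ± 0.832 CPM. Cytosolic ribosomal protein genes rose in 24 of 41 cases and fell in 2 (26 and 2 adjusted over the list alone; median 0.19, camera adjusted p = 0.00021, and adjusted p = 0.83 with an estimated correlation). RPS16 rose 1.52-fold, RPS6 from 883.3 ± 53.6 to 1233 ± 104 CPM and RPL18 1.32-fold. The 2 that fell, RPLP1 and RPL4, both lie on chromosome 15, and the call of RPL4 was lost without any of 5 libraries (all but WT replicate 3), with rescaling to column totals and without the variance trend. With the regional median subtracted it reversed to 0.37. Mitochondrially encoded transcripts made up 0.90% to 0.99% of CPM in every library. Of the 12 listed, 4 rose and 3 fell (camera adjusted p = 0.96), among them MT-ND3, which rose by 0.41 on the log2 scale. Of 8 listed nuclear-retained long RNAs, 5 rose and 1 fell (median 0.32, camera adjusted p = 0.33). SNHG14 rose 9.94-fold and OIP5-AS1 fell 2.12-fold, and both lie on chromosome 15. Of 11 abundant small structural RNAs, 3 rose and 0 fell (1 and 0 adjusted over the list alone; median 0.13, camera adjusted p = 0.43). Among them, RN7SL1 rose 1.32-fold, a call that was lost without WT replicate 2 (adjusted p = 0.15), MSLN-KO replicate 1 (0.14) or MSLN-KO replicate 2 (0.11).

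**Figure D2:**
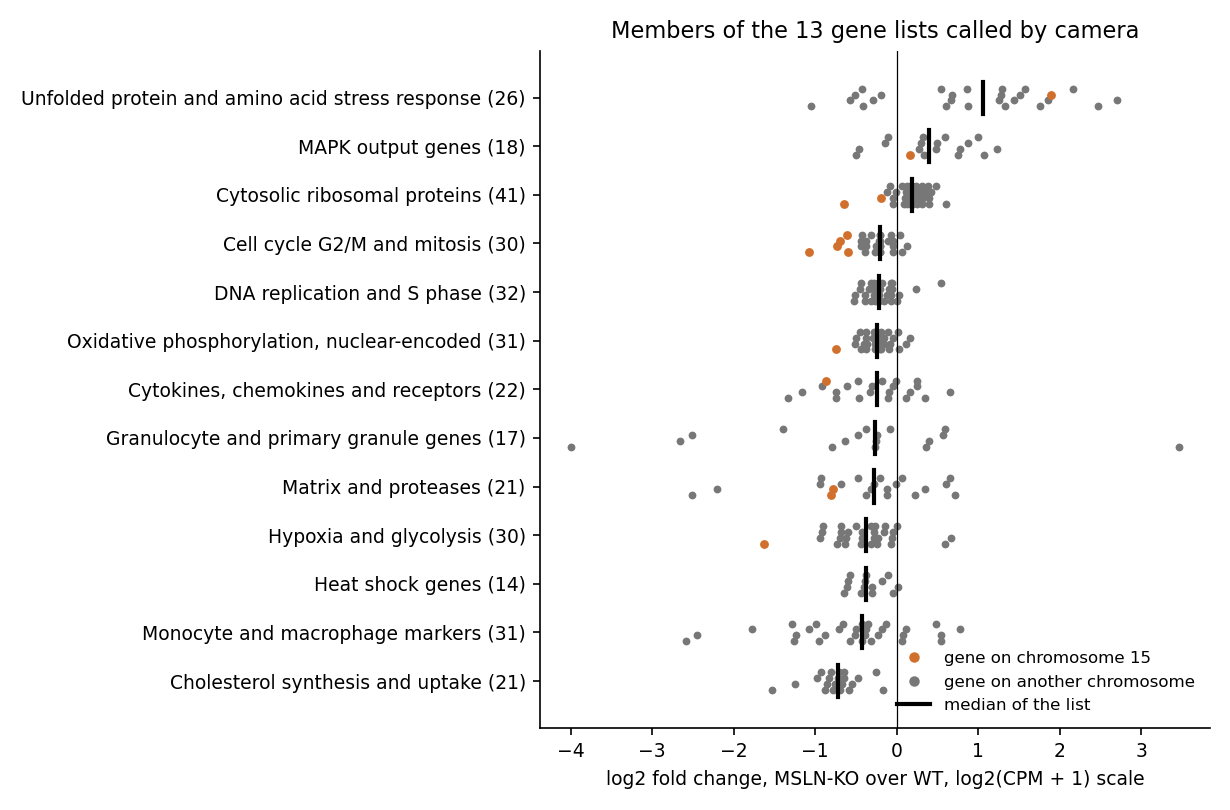
Log2 fold change of MSLN-KO over WT (x axis, log2(CPM + 1) scale) for each listed member of the 13 gene lists called by camera (y axis, number of listed members in brackets). Points are genes, orange on chromosome 15 and grey elsewhere, and black bars are list medians, from -0.72 for cholesterol synthesis to 1.06 for the stress response list.

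Lists that the camera test did not call held single large changes. Targets of KMT2A fusions had 6 rises, 4 falls and 11 members not called among 21 (median 0.05, adjusted p = 0.63), with LAMP5 higher 2.23-fold and CPEB2 1.99-fold. In the list of genes linked to mesothelin in solid tumours, 7 rose and 8 fell among 21 (adjusted p = 0.96). In it, CD276, on chromosome 15, fell 2.71-fold. Among AML surface antigens and immunotherapy targets, CD38 rose from 10.31 ± 0.736 to 42.54 ± 1.32 CPM and the NKG2D ligand gene ULBP1 rose 5.77-fold (7 rises and 7 falls among 18, adjusted p = 0.96). Of the MHC class I genes, B2M fell from 2102 ± 107 to 997 ± 34.5 CPM and PDIA3 fell 2.27-fold, and both lie on chromosome 15 (4 rises and 7 falls among 17, adjusted p = 0.33). IFITM1 rose 6.80-fold in a list of interferon-stimulated genes with 9 rises and 7 falls among 21 (adjusted p = 0.70). Replication-dependent histones had 11 rises and 4 falls among 44 (median 0.05, adjusted p = 0.35) and passed only without MSLN-KO replicate 3 (median 0.13, adjusted p = 0.0083, within a range up to 1 over all alternatives). GPI-anchor synthesis genes, which build the anchor that mesothelin carries, had 6 rises and 3 falls among 25 (adjusted p = 0.71).

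Markers of other cell types were few. Of the lists for T and NK cells, B cells, erythroid and megakaryocytic cells, epithelial and mesothelial cells, and stromal and endothelial cells, 1, 3, 3, 1 and 2 members were listed, all with a mean of at least 1 CPM, too few for a list test. The most abundant were NKG7 (36.1 CPM), FCRLA (17.5 CPM), TFRC (318 CPM), KRT18 (8.44 CPM) and PECAM1 (450 CPM). TFRC, the transferrin receptor gene, fell from 474.3 ± 35.6 to 162.1 ± 9.66 CPM, CD79B fell 3.67-fold, ITGA2B rose 4.08-fold and BANK1 rose 2.19-fold.

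Expression also differed between the groups by position in the genome, a pattern examined only after the values were seen. On 9p, all 7 listed genes from FOCAD to C9orf72 (GRCh38 chromosome 9, 20658309 to 27573866, 6.92 Mb) had 0 reads in each of the 3 WT libraries. In MSLN-KO they stood at 6.6 to 18.1 CPM: FOCAD, HACD4, KLHL9, MTAP, CAAP1, PLAA and C9orf72 were at least 315-, 447-, 342-, 439-, 162-, 293- and 281-fold higher. MTAP encodes an enzyme of methionine salvage and lies beside the CDKN2A locus. The flanking listed genes, MLLT3 (7.019 ± 0.94 CPM in WT and 6.724 ± 0.981 CPM in MSLN-KO, adjusted p = 0.74) and ACO1 (log2 change 0.18, adjusted p = 0.052), were not called. MLLT3 is also the fusion partner of KMT2A in this line. Gene-level values do not separate reads of the fusion from those of the locus on 9p.

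**Figure D3:**
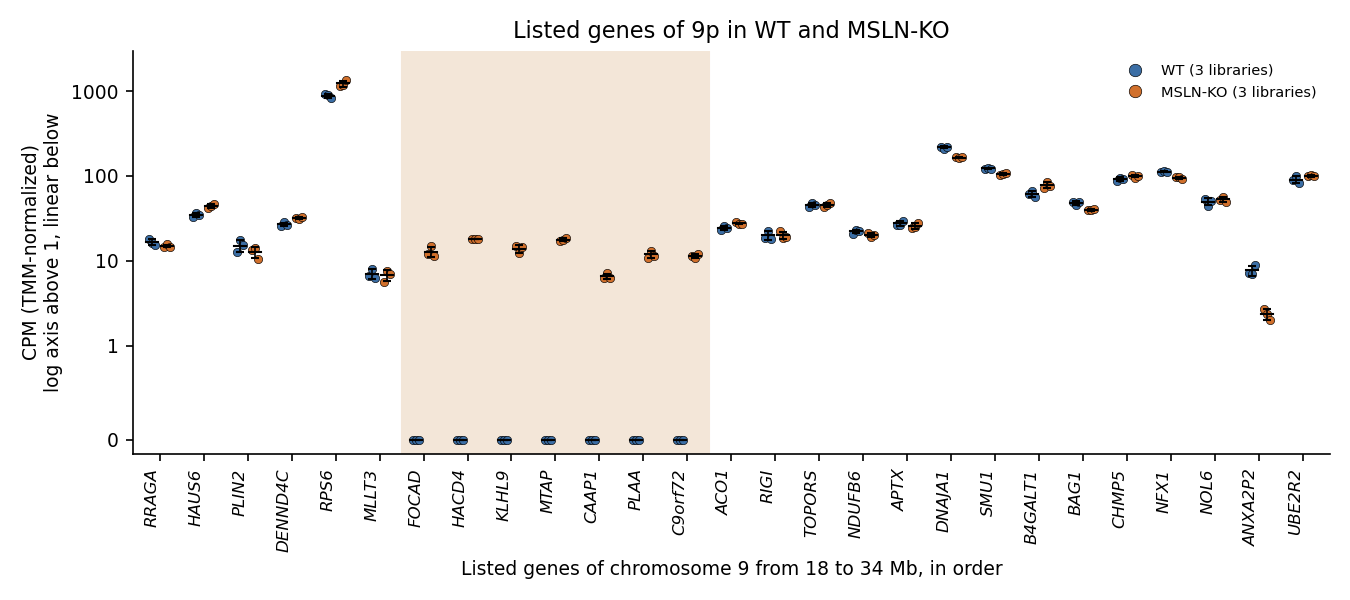
Normalized expression (y axis, CPM, linear below 1 and logarithmic above) of the 27 listed genes of chromosome 9 lying between 18 and 34 Mb, in order of position (x axis), in WT (blue) and MSLN-KO (orange). Points are libraries, and bars are the mean ± SD of 3. The 7 shaded genes were at 0 in all WT libraries and between 6.6 and 18.1 CPM on average in MSLN-KO.

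A group of zinc finger genes at 19p12 showed a similar contrast. Of the listed genes there, 16 lie from ZNF486 to ZNF254 (chromosome 19, 20167228 to 24129961). Among them, 8 rose by 2.89 or more on the log2(CPM + 1) scale, 7 were not called and 1 (ZNF724) rose by 0.62. ZNF486, ZNF737, ZNF85, ZNF43 and ZNF675 had 0 reads in WT and were at least 245-, 161-, 176-, 427- and 196-fold higher. The 7 that were not called lie between them and stood at 10.8 to 57.6 CPM in WT. Outside both regions, H4C6, PURPL and PPP1R3A had 0 reads in WT (at least 550-, 274- and 209-fold higher). That makes 15 reported genes at 0 in all WT libraries, against 0 in all MSLN-KO libraries.

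Chromosome 15 was lower as a whole. Its 371 listed genes had a median log2 change of -0.57, 92.2% of them lay below 0, and 307 were called lower and 13 higher. Medians of the other chromosomes from 1 to X lay between -0.10 (chromosome 8) and 0.15 (chromosome 19). Along chromosome 15 the median of 41 neighbouring genes ran from -0.71 to -0.40. They made up 307 of the 2652 genes called lower in MSLN-KO. Without genes of the chromosome, 4841 genes were called. All 13 lists above still passed the camera test when its genes were left out, and 1 more did: oxidative stress and NRF2 targets (17 listed, 0 on chromosome 15, 2 higher and 6 lower), with a median of -0.16 and an adjusted p of 0.071 in the main fit and 0.037 here. With the regional median subtracted it was 0.026, within a range of 0.026 to 0.76 over all alternatives. The naming rule selected 18 lower genes on this chromosome, and 11 of them kept less than 0.5 of their log2 change once the regional median was subtracted. Those changes went from -1.07 to -0.49 for CCNB2, from -0.73 to -0.21 for NUSAP1, from -0.69 to -0.21 for KIF23, from -0.75 to -0.25 for COX5A, from -0.87 to -0.22 for IL16 and from -0.65 to -0.18 for RPLP1. PKM (-1.63 to -1.15), CD276 (-1.41 to -0.93), PDIA3 (-1.18 to -0.62) and B2M (-1.07 to -0.54) kept more. Because a similar amount was subtracted from each gene, smaller falls tended to keep a smaller share.

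**Figure D4:**
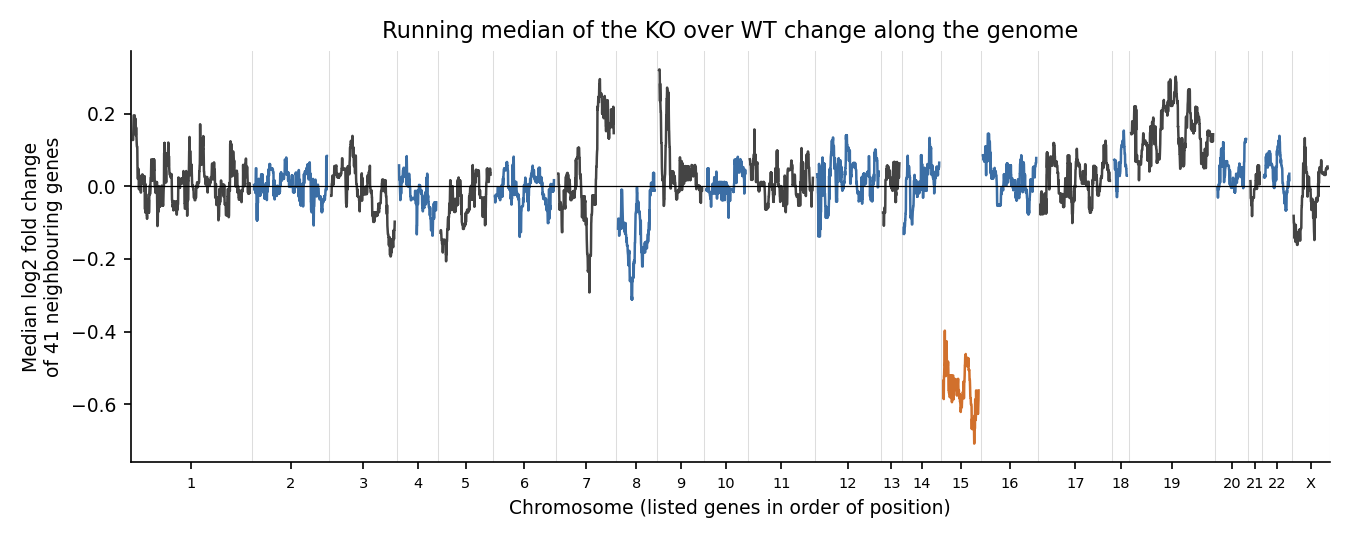
Running median of the log2 fold change of MSLN-KO over WT in windows of 41 neighbouring listed genes (y axis) along chromosomes 1 to 22 and X, genes in order of position (x axis). Chromosome 15 (orange) lies between -0.71 and -0.40. Other chromosomes stay between -0.31 and 0.32.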

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

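The fits without chromosome 15 and with the regional median subtracted were chosen after the data were seen. MSLN kept its direction and its call under all 17 alternatives (-1.56 to -1.29), and the count of called genes stayed between 4092 (without MSLN-KO replicate 1) and 5220, of which 4050 and 4823 were shared with the main 5197. Leaving out single libraries gave 361 to 407 genes with a log2 change of at least 1, 13 to 14 lists, and a median of 0.13 to 0.34 for the neighbours of MSLN. With a pseudocount of 5, 244 genes passed that bar, since a larger pseudocount shrinks the change of low genes. Camera called 0 lists with an estimated correlation and fry 37 in its mixed form, which asks another question; the other list calls that were lost or gained are given in the results, and their cause was not tested. Rescaling to column totals put 56.4% of calls on the higher side, against 49.0%, and moved the median gene to 0.039. Of 142 named genes, 7 lost their call under some alternative and 1 reversed: RPL4 was 0.37 with the regional median subtracted, since its neighbours on chromosome 15 were lower still. No filter on low values removed no gene, so that setting tests nothing. The replicate block gave 4946 calls and also ended the call of RPL4 (adjusted p = 0.056). Same-numbered libraries did not deviate together (correlations 0.192, -0.169 and -0.092), and not every library correlated best with its own number, so the numbers were not taken as pairs. The planned edgeR and DESeq2 fits on whole reads were not run, because only 7 to 30 values per library stand at 1 to 20 reads, too few for the check set for count fits; counting noise was thus not modelled here. On simulated libraries of this depth, with 1 spread for all genes, 70% of genes at the smallest fold tried were recovered. That rate need not hold for the real genes. Genes under about 4.9 CPM in both groups were not analysed here.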

Other observations

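The genes named in this and the next paragraph, except SNHG14, were chosen after their values were seen. All 13 genes were called (limma, adjusted p at most 5.3e-08), with no overlap between the groups. ALDH1L2 rose from 7.429 to 87.4 CPM, BCAT1 from 16.76 to 80.98, GPT2 from 11.79 to 54.43 and CBS from 0.1365 to 9.397 CPM. The transcription factor gene ATF5 rose from 5.249 to 40.07 CPM. FOXP2 rose from 1.527 to 25.01 CPM, and the T cell receptor gamma constant genes TRGC1 and TRGC2, a near-identical pair, from 6.627 to 44.31 and from 2.009 to 37.98 CPM. The lipoprotein lipase gene LPL fell from 67.33 to 10.86 CPM and the connexin gene GJB2 from 30.43 to 3.613 CPM. TP63 fell from 18.67 to 2.968 CPM.

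The imprinted genes SNHG14 and SNRPN at 15q11 went against the lower level of chromosome 15 in MSLN-KO. The level of 15q11 itself was not measured apart from the rest of the chromosome. SNHG14 rose from 10.02 ± 2.06 to 99.61 ± 6.64 CPM and SNRPN from 8.511 to 40.4 CPM. Smaller regional shifts were seen on chromosome 7, where windows of 41 genes ran from -0.29 to 0.30, on chromosome 8 (down to -0.31), on chromosome 9 (up to 0.32) and on chromosome 19 (0.02 to 0.30).

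The tests of the 3 patterns below were chosen after the results were seen; the count of splits was planned. Of the 10 splits of the 6 libraries into 3 and 3, the real split gave 5197 called genes and the highest of the others 0. The real split was the only 1 with as many, but 10 splits are too few for a share under 0.05.

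The first pattern is the set of genes without reads in WT. Low depth is argued against, since the least expressed of the 7 genes on 9p would have had 487 reads in WT at its MSLN-KO level. A high number was bound to appear, since every listed gene at 0 in WT reached at least 4.9 CPM in each MSLN-KO library. For a swap between the groups, 0 libraries were out of place. The genes were chosen for 0 reads in every WT library, so that count could not show a swap. Loss of a stretch of DNA on 9p in the cells of the WT libraries is a candidate explanation. RNA alone does not separate lost from silenced DNA. The stretch was bounded by its own genes at 0, so the 0 reads of all 7 listed genes are no independent test. No listed gene lies between MTAP, which ends at 21937651, and CAAP1, which starts at 26840685. A single lost stretch does not account for 19p12, where 11 of the 16 listed genes had more than 3 reads in WT. Among those 11, ZNF493 and ZNF254 had only 4 reads each over the WT group and ZNF91 had 37. The weight lies on the 7 genes not called, which stood at 10.8 to 57.6 CPM in WT. Whether the WT and MSLN-KO cells came from different lines or sub-lines, or changed after the edit, cannot be told apart here. Any difference of line or sub-line goes with the genotype in these libraries. In WT, 3 reads over the 9p genes would allow at most 0.044% of the cells to express them as MSLN-KO cells did. These genes set no such limit on the mix of cells in MSLN-KO. An effect of losing MSLN stays open as well, for genes silenced rather than lost in the WT cells, and was not tested.

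The second pattern is the lower level of chromosome 15 in MSLN-KO. The median of genes on the other chromosomes, 0.016, had to lie near 0 after TMM normalization and decides nothing alone. A scaling factor of a whole library moves all chromosomes nearly alike, so the gap to -0.57 on chromosome 15 argues against one. A few strongly lowered genes are argued against by the 92.2% of the chromosome's listed genes below 0. A copy number difference of the whole chromosome is a candidate explanation: the highest median of 41 neighbouring genes was -0.40, and the chromosome's median of -0.57 lies near the -0.58 that 2 copies against 3 would give. No copy number was measured, and an effect of the knockout on the whole chromosome was not tested. Changes of single genes on it may hold such a dosage part, which was not tested. With the regional median subtracted, 11 of the 18 lower genes that the naming rule selected there kept less than 0.5 of their log2 change. PRC1 went from -0.61 to 0.00, and RPL4, which reversed to 0.37, is counted among the 11. A similar amount was taken from each gene, so this count mainly follows from the size of each fall and is no support for a dosage part.

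The third pattern is the MSLN transcript left in MSLN-KO. Cells like those of the WT libraries mixed into the MSLN-KO libraries are argued against as the whole source, since they would bring every WT transcript at the share MSLN keeps. Genes of at least 10 CPM that kept less than 0.5 of the share of MSLN were chosen in 1 WT and 1 MSLN-KO library, and the other libraries were then read. Over the 9 choices of those libraries 12 to 26 genes were chosen, and 12 to 16 of them stayed under that bar in both other MSLN-KO libraries. A first form of this test, which asked for 5 genes of at least 100 CPM and chose and read them in the same libraries, had found 2 (MPO and DEFB1) among 2098, and a second form read those 2 alone and is not used. A lower copy number of the region is argued against by the median log2 change of 0.09 within 1 Mb. That median would not show a loss confined to MSLN or to a part of it, which was not tested. Unedited cells of a sub-line other than that of the WT libraries may contribute to the 36.1% that remained and cannot be excluded, because no library of such cells was measured, and a transcript that persists after an edit that disrupts the protein was not tested.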
